A study of Mus musculus with 8 samples.

How the data were processed

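RNA of mouse embryonic fibroblasts, a primary cell culture grown from mouse embryos, was measured on 8 Affymetrix whole-genome expression arrays for the mouse. Per the labels' protocols, control cells and cells lacking both Stat5a and Stat5b were used at passage 13, starved for 5 hours and then stimulated with growth hormone (GH) at 1 ug/ml or left without it for 2 hours. RNA was extracted with a column kit, and biotin-labelled cRNA was prepared by the standard Affymetrix protocol, per the labels' protocols. The 4 groups hold 2 arrays each, which the labels number 2 and 3 and call biological replicates. Groups and numbers were taken from the array titles. For 1 array of null cells without GH the source label carries the number 3 while the title carries 2, and the title was used.

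The deposited values are on the log2 scale, from the robust multi-array average (RMA), per the submitters' processing notes, which name Partek 6.10.0511 and RMA. RMA corrects each array for background, equalises the distributions of the arrays and summarises the probes of each probe set. The settings are not given in the sources used here. The deposited log2 values carry no detection call, so a dim probe set was not set apart from background. Where a gene's mean in 1 of the groups compared lay below the first quartile of all gene values, the report gives at most the brighter level for that comparison, and neither the size nor the rank of the change. The closing section prints 4 interaction values of such genes and takes only their direction. This limit was chosen after the data were seen. Array medians lay between 6.89 and 6.96 on the log2 scale. For arrays, the number of replicates limits the precision, and the median residual SD of a gene was 0.097 on the log2 scale.

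The table holds 45101 probe sets, of which 64 controls were left out. Of the other 45037, the platform annotation gave 1 gene for 34945, several genes for 932 and none for 9160. Probe sets with several genes or none stayed unnamed and out of the gene tests. Symbols were brought up to date through Entrez identifiers for 34741 probe sets, using the gene table of the mouse assembly GRCm38.p6 for names only, and 204 kept the annotated name. Where a gene had several probe sets, as 9010 genes did, the one with the highest mean over all arrays was used. This left 18193 genes. No genomic coordinates are given, because no source used here names a genome build for the probe sets.

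All 8 arrays were fitted with 1 mean per group in limma 3.58.1 (R 4.3.3), which left 4 residual degrees of freedom, with moderation of the gene variances (7.82 prior degrees of freedom, prior SD 0.101). The 7 comparisons were null against control without GH, null against control with GH, GH against none in control cells, GH against none in null cells, the difference between the last 2 (the interaction), and both effects averaged over the other factor. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, and every adjusted p for a gene is limma's. The errors printed with log2 differences are limma's standard errors (SE), with 2 arrays per group. Data were simulated for 18193 genes with 1 mean per gene and independent noise of the fitted spread. In each comparison 50 genes were changed at each of the log2 sizes 0.5, 1, 2 and 4. Changes of 1 or more were recovered in 100% of cases in every comparison. Changes of 0.5 were recovered in 90% of cases for null against control without GH, 72% for GH in control cells, 86% for GH in null cells and 28% for the interaction. False calls made up 8.02%, 3.12%, 5.39% and 7.87% of the calls in these comparisons. Far more genes were called in the real data, such as 47.49% for null against control without GH. The simulated shares therefore do not carry over to the real calls.

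Before the data were examined, 27 lists were fixed: STAT5 and GH target genes, GH receptor and JAK-STAT components, CDK inhibitors, p53 target genes, G1/S and DNA replication genes, G2/M genes, the BCL2 family, immediate early genes, STAT3 target and acute phase genes, interferon response genes, chemokines and inflammatory genes, extracellular matrix genes, TGF-beta and myofibroblast genes, growth factors and the IGF system, oxidative stress genes, cholesterol and fatty acid synthesis genes, HOX genes, neighbours of Stat5a and Stat5b on chromosome 11, sex-linked genes, and markers of fibroblasts, epithelium, endothelium, macrophages and leukocytes, adipocytes, skeletal muscle, neural and glial cells, and cartilage and bone. Each list was set against all other genes with limma's camera test at a preset correlation of 0.01 between genes, and adjusted over the 27 lists of a comparison. The same test was run with a correlation estimated from the residuals. Members past the gene test were counted after adjustment over all genes and after adjustment over the list alone.

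Genes were named by a rule also fixed beforehand. Stat5a, Stat5b, Cdkn2b, Cdkn1a, Cish, Socs2, Socs3, Igf1 and Bcl6 were followed in every comparison. The 10 genes that rose and the 10 that fell with the largest changes were named for null against control without GH, and the 5 and the 5 for each other comparison. Such genes had to be called, their arrays could not overlap between the groups, and symbols of the kind given to predicted genes or clones were passed over, among them any that start with C, D or E and a digit. That pattern also passed over C1qa, C1qb and C1qc. Up to 4 members per list, those with the lowest p, were named as well. The alternatives tried were a block for the replicate number, a fit on only the arrays compared, a trended robust prior, no variance moderation, quantile normalization, equal array medians, every probe set tested alone, the mean of a gene's probe sets, genes above the median only, a minimum change of 1.5-fold, and each array left out in turn. A block with crossed replicate numbers was added after the data were seen. Figures were drawn with matplotlib.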

Results

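The data collected were genome-wide expression values of mouse embryonic fibroblasts of 2 genotypes, each with and without a short exposure to growth hormone. GH acts through its receptor and the kinase JAK2, which activates the transcription factors STAT5A and STAT5B. The series title names as its subject the restraint of proliferation by STAT5 through the cell cycle inhibitor genes Cdkn2b and Cdkn1a. Control cells without GH, control cells with GH, Stat5a/b-null cells without GH and null cells with GH were each measured on 2 arrays. Replicate arrays correlated at 0.997 or 0.998 across all probe sets. Group means correlated at 0.964 between the genotypes in either GH state, at 0.996 between control cells with and without GH and at 0.993 between null cells with and without GH. The labels call the replicates biological but do not say whether they came from separate embryos or cultures, so the p-values measure the spread between these arrays.

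The transcripts of the deleted genes were examined first. Both probe sets of Stat5a were lower in null than in control cells without GH. They stood at 7.49 and 7.14 in control cells and below the first quartile of all gene values, a level not set apart from background, in null cells, so the size of the difference is not given. The same holds for 1 of the 2 probe sets of Stat5b, at 8.47 in control cells. The other Stat5b probe set had the higher mean and stood for the gene in the tests (-0.69 ± 0.09, adjusted p = 3.33e-05). Which part of either gene was deleted is not given in the sources used here, so a probe set that still gave signal does not show that the protein was made.

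Cdkn1a, which encodes the cell cycle inhibitor p21, was 18.9-fold lower in null than in control cells without GH (log2 difference -4.24 ± 0.10, adjusted p = 9.77e-12). Its mean was 13.82 ± 0.09 (SD, n = 2) on control arrays and 9.57 ± 0.07 (SD, n = 2) on null arrays. Cdkn2b, which encodes the inhibitor p15, was 2.04-fold lower (-1.03 ± 0.09, adjusted p = 1.24e-06). The other inhibitor genes went both ways: Cdkn1c was lower (-2.58 ± 0.12), whereas Cdkn1b (2.09 ± 0.11) and Cdkn2c (1.70 ± 0.09) were higher in null cells. Of the 8 CDK inhibitor genes, 4 were higher and 3 lower, also when adjusted over the list alone, and the list as a whole was not shifted (adjusted p = 0.989, median 0.23, mean -0.34).

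Without GH, the targets of the tumour suppressor p53 were lower in null cells, with 22 of 26 measured members lower and 2 higher, the same counts as when adjusted over the list alone. They had a median log2 difference of -1.85 (camera adjusted p = 8.13e-13, and adjusted p = 0.0728 with an estimated correlation). Among them were the nuclease gene Aen (-3.62 ± 0.10), and the apoptosis gene Pmaip1 and the desmosomal gene Perp, which stood at 10.95 and 9.56 in control cells and below the first quartile in null cells. Mitotic genes were higher in null cells, with 27 of 33 G2/M genes higher and none lower, and 28 higher adjusted over the list alone (median 0.74, adjusted p = 7.89e-10, and adjusted p = 0.105 with an estimated correlation). Cdc25b, a phosphatase that activates CDK1, was 4.46-fold higher (2.16 ± 0.11), and the spindle and kinetochore genes Nusap1 (1.81 ± 0.09), Cenpa (1.82 ± 0.12) and Bub1b (1.42 ± 0.09) were higher too. The G1/S and DNA replication list was not shifted (15 higher and 9 lower of 37, 16 and 9 adjusted over the list alone, adjusted p = 0.709). Within it the D-type cyclin genes Ccnd1 (-1.13 ± 0.09) and Ccnd2 (-1.61 ± 0.10) were lower and the replication factor gene Rfc4 was higher (1.98 ± 0.13).

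Genes of cholesterol and fatty acid synthesis were higher in null cells without GH. Of 22 measured, 18 were higher and 1 lower (19 and 1 adjusted over the list alone, median 0.88). Members with the lowest p included Elovl6 (1.73 ± 0.10), Idi1 (1.60 ± 0.11) and Fdps (1.48 ± 0.08). The shift had an adjusted p of 4.45e-07, and an adjusted p = 0.296 with an estimated correlation. TGF-beta and myofibroblast genes were lower, with 21 of 29 lower and 6 higher (22 and 6 adjusted over the list alone, median -0.57). Examples were Inhba, an activin subunit (-3.27 ± 0.14), the matricellular gene Ccn2 (-2.11 ± 0.09), and the smooth muscle genes Cnn1 (-2.11 ± 0.11) and Actg2 (-1.70 ± 0.08). The adjusted p was 0.000232, and adjusted p = 0.173 with an estimated correlation.

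Markers of another cell type moved with these groups. All 10 macrophage and leukocyte markers were lower in null cells without GH, also when adjusted over the list alone (median -2.56, adjusted p = 4.98e-10, and adjusted p = 0.105 with an estimated correlation). The lysozyme gene Lyz2 was 40.1-fold lower (-5.32 ± 0.10), and the signalling adaptor gene Tyrobp was lower by a log2 difference of -5.17 ± 0.12. The Tyrobp values on the null arrays (6.31 and 6.179) lay close to the first quartile. The leukocyte surface gene Ptprc (CD45) stood at 9.20 in control cells and below the first quartile in null cells. Averaged over the GH states, Lyz2 stood at 13.87 on control and 8.56 on null arrays, against a median of 8.04 for all gene values. The 12 fibroblast markers were not shifted without GH (3 higher, 1 lower, the same adjusted over the list alone, median 0.09, adjusted p = 0.281).

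Of the 18193 genes tested, 8640 differed between null and control cells without GH (4510 higher and 4130 lower in null). At least 2-fold differences were found for 1012 genes higher and 1116 lower, and at least 4-fold for 205 and 284. Among the genes with large differences, the stromal gene Islr (47.3-fold), the alcohol dehydrogenase gene Adh1 (37.1-fold) and Mgst2 (35.4-fold) were higher in null cells. Grb10, an adaptor that restrains insulin and IGF receptor signalling (94.3-fold), the actin gene Acta1 (58.5-fold), Cthrc1 (52.1-fold) and the cathepsin gene Ctsc (45.6-fold) were lower. The other probe sets of Grb10 gave smaller differences in this and the later genotype comparisons, such as -3.40 here. The other probe sets of Ctsc were lower too but dim in both genotypes. The null mean of the Ctsc probe set used (6.23) lay close to the first quartile. Other genes named by the same rule lay below the first quartile in 1 genotype, so the size and the order of their differences are not given. Higher in null cells, with their null means, were the angiopoietin-like gene Angptl1 (11.22), the angiotensin receptor gene Agtr2 (11.15), the ferritin receptor gene Scara5 (11.25), the cartilage matrix gene Cilp (10.89), the Wnt modulator gene Sfrp2 (11.11), Greb1 (10.80) and the oestrogen receptor gene Esr1 (10.51). Lower in null cells, with their control means, were Efemp1, which encodes the matrix protein fibulin-3 (12.31), the ribosomal protein paralogs Rpl39l (11.35) and Rps4l (10.84), the cathepsin gene Ctss (11.48), the G protein gene Gnai1 (10.19) and the IGF-binding protein gene Igfbp2 (11.46). The complement genes C1qa, C1qb and C1qc, at 12.06, 11.77 and 11.37 in control cells, were also lower but were passed over by the naming rule. For Angptl1, 1 of its 3 probe sets, and for Scara5, 1 of its 2, was not past the threshold. Among known GH targets, Igf1 was higher in null cells without GH (5.00-fold, 2.32 ± 0.09), as were Bcl6 (1.17 ± 0.11) and Socs3 (0.78 ± 0.11), whereas Socs2 (-1.18 ± 0.10) and Cish (-0.60 ± 0.11) were lower. Requiring a change of at least 1.5-fold left 4521 genes (2254 higher, 2267 lower), and testing each probe set alone called 17383 (8577 higher, 8806 lower), so neither direction led under every setting.

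Other gene groups, except cartilage and bone markers, held members that went both ways without GH, and 22 lists in all were not called (adjusted p from 0.0684 to 0.989). Counts of members higher and lower in null cells were 8 and 8 of 20 STAT5 and GH target genes, 6 and 9 of 22 JAK-STAT components, 2 and 7 of 14 BCL2 family genes and 13 and 10 of 35 immediate early genes. They were 10 and 8 of 22 STAT3 target genes, 13 and 8 of 36 interferon response genes, 11 and 14 of 30 chemokine and inflammatory genes and 14 and 16 of 37 extracellular matrix genes. Adjusted over the list alone these were 8 and 8, 6 and 9, 2 and 7, 13 and 11, 11 and 8, 14 and 8, 11 and 14, and 14 and 17. Growth factors and the IGF system had 9 and 10 of 23, oxidative stress genes 8 and 5 of 18, HOX genes 10 and 12 of 30, the chromosome 11 neighbours of Stat5a and Stat5b 8 and 9 of 32 and sex-linked genes 1 and 1 of 7 (10 and 10, 9 and 5, 10 and 12, 8 and 9, and 1 and 1 adjusted over the list alone). Epithelial markers had 1 and 2 of 10, endothelial markers 1 and 5 of 10, adipocyte markers 3 and 3 of 8, skeletal muscle markers 4 and 3 of 12, neural and glial markers 1 and 3 of 9, and cartilage and bone markers 3 and 0 of 8 (1 and 2, 1 and 5, 3 and 3, 4 and 4, 1 and 3, and 3 and 0 adjusted over the list alone).

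**Figure D1:**
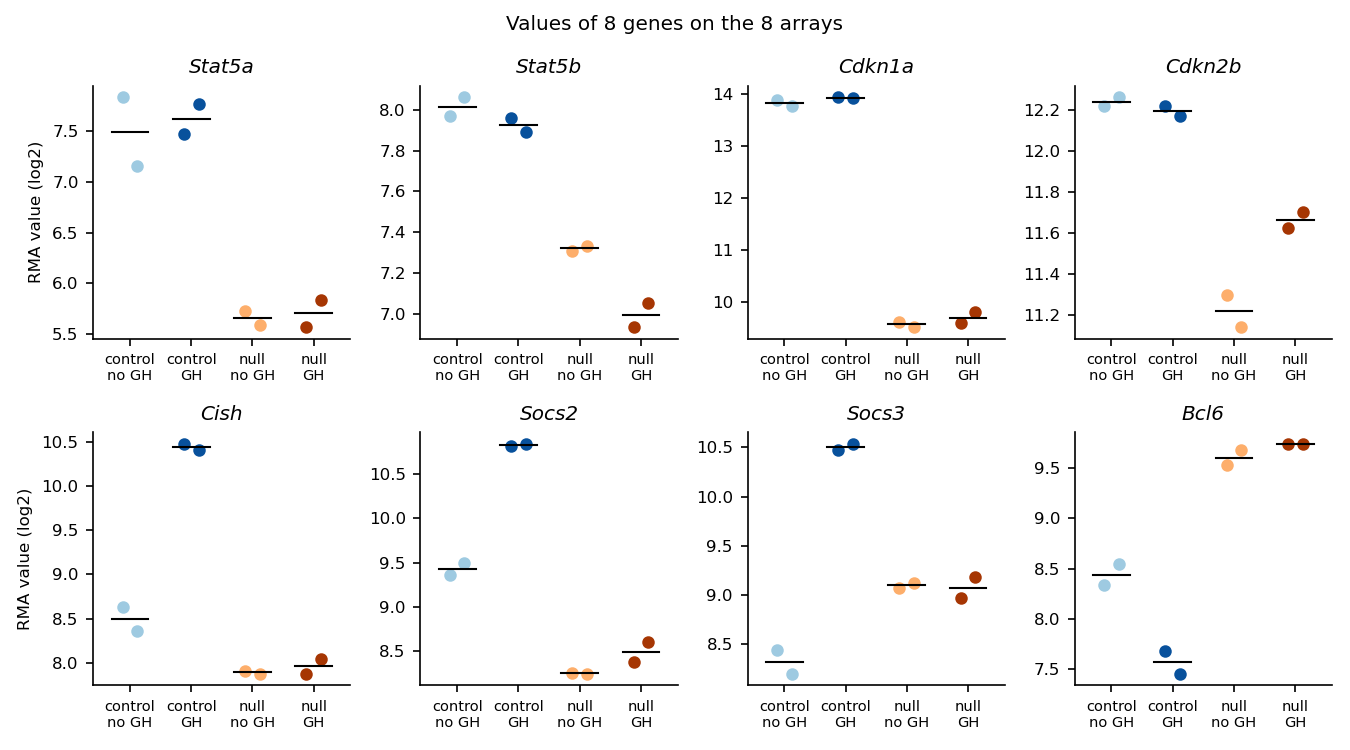
Deposited RMA values (log2, vertical axes with a separate range for each gene) of Stat5a, Stat5b, Cdkn1a, Cdkn2b, Cish, Socs2, Socs3 and Bcl6 on the 8 arrays. Points are single arrays and bars are means of the 2 arrays of a group, such as 13.82 for Cdkn1a in control cells without GH and 9.57 in null cells without GH.

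In the presence of GH the genotypes differed in 8247 genes (4042 higher and 4205 lower in null). Cdkn1a was 18.6-fold lower in null cells (-4.22 ± 0.10, adjusted p = 8.47e-12) and Cdkn2b 1.45-fold lower (-0.53 ± 0.09, adjusted p = 0.000327). The feedback inhibitor genes of cytokine signalling were all lower in null cells with GH: Cish by a log2 difference of -2.49 ± 0.11, Socs2 of -2.35 ± 0.10 and Socs3 of -1.43 ± 0.11. Bcl6, a transcriptional repressor gene, was 4.52-fold higher and Igf1 5.15-fold higher, while Stat5b (-0.93 ± 0.09) was lower, as was Stat5a, at 7.62 in control cells and below the first quartile in null cells. Islr (5.27) and Mgst2 (5.20) were higher and Grb10 (-7.11) was lower in null cells. Angptl1, Agtr2 and Scara5 (null means 11.11, 11.09 and 11.22) were higher, and Efemp1, the chemokine gene Ccl3, Cthrc1 and Ctss (control means 12.49, 11.92, 12.25 and 11.28) were lower, each against a level below the first quartile.

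In the presence of GH, p53 targets were lower (21 lower and 2 higher of 26, the same adjusted over the list alone, adjusted p = 2.58e-11, and adjusted p = 0.0918 with an estimated correlation). TGF-beta and myofibroblast genes were lower (20 lower and 7 higher of 29, the same adjusted over the list alone, adjusted p = 0.00639, and adjusted p = 0.278 with an estimated correlation). All 10 macrophage markers were lower (10 adjusted over the list alone, median -3.05, adjusted p = 1.78e-10, and adjusted p = 0.115 with an estimated correlation). G2/M genes were higher (24 of 33, 24 adjusted over the list alone, adjusted p = 3.14e-08, and adjusted p = 0.148 with an estimated correlation). Cholesterol and fatty acid synthesis genes were higher (17 higher and 1 lower of 22, 19 and 1 adjusted over the list alone, adjusted p = 1.21e-08, and adjusted p = 0.265 with an estimated correlation). Immediate early genes were higher as well (20 higher and 9 lower of 35, 21 and 9 adjusted over the list alone, adjusted p = 0.0233, and adjusted p = 0.476 with an estimated correlation). Among these immediate early genes the lowest p belonged to Btg2 (-2.12 ± 0.09), Egr1 (2.42 ± 0.10), Ccn1 (2.18 ± 0.10) and Spry2 (2.25 ± 0.14). The other 21 lists were not called (adjusted p from 0.0518 to 0.829).

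The same 3350 genes were higher and the same 3374 lower in null cells in both GH states, where independent lists of these sizes would share 1002 and 954.6. Across genes, which are not independent replicates, the log2 differences in the 2 GH states correlated at 0.921. These comparisons share no array, but both set the same genotypes against each other and use a shared residual variance. Much of this overlap follows from the design and is not independent replication. Averaged over the GH states, 9926 genes differed (5048 higher, 4878 lower). Islr (5.42 ± 0.07) was higher and Grb10 (-6.83 ± 0.06) lower in null cells. Angptl1, Agtr2, Scara5 and Cilp were higher, and Efemp1, Ctss, Rpl39l and Cthrc1 lower, against a dim level in the other genotype. In the average, 23 of 26 p53 targets were lower and 2 higher (the same adjusted over the list alone, median -1.97, adjusted p = 2.29e-11, and adjusted p = 0.091 with an estimated correlation). Cdkn1a (-4.23 ± 0.07), Cdkn2b (-0.78 ± 0.06), Stat5b (-0.81 ± 0.06), Cish (-1.54 ± 0.07), Socs2 (-1.76 ± 0.07) and Socs3 (-0.33 ± 0.08) were lower, as was Stat5a against a dim level. For Socs3 the average covers opposite differences, higher in null cells without GH (0.78) and lower with GH (-1.43). Igf1 (2.34 ± 0.06) and Bcl6 (1.67 ± 0.08) were higher.

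The average also showed 27 of 33 G2/M genes higher (28 adjusted over the list alone, adjusted p = 3.76e-09, and adjusted p = 0.119 with an estimated correlation) and 20 of 22 cholesterol and fatty acid synthesis genes higher and 1 lower (the same adjusted over the list alone, adjusted p = 6.69e-08, and adjusted p = 0.25 with an estimated correlation). TGF-beta and myofibroblast genes were lower, 22 against 7 higher of 29 (the same adjusted over the list alone, adjusted p = 0.00122, and adjusted p = 0.238 with an estimated correlation). All 10 macrophage markers were lower (10 adjusted over the list alone, median -2.81, adjusted p = 3.35e-09, and adjusted p = 0.119 with an estimated correlation). Changes of at least 1.5-fold were seen for 4369 genes with GH and 4303 (2111 higher, 2192 lower) in the average. With each probe set tested alone, 16797 (8841 higher, 7956 lower) and 20810 were called, so here too the direction with more genes was not settled. In the average 22 lists were not called (adjusted p from 0.115 to 0.926).

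**Figure D2:**
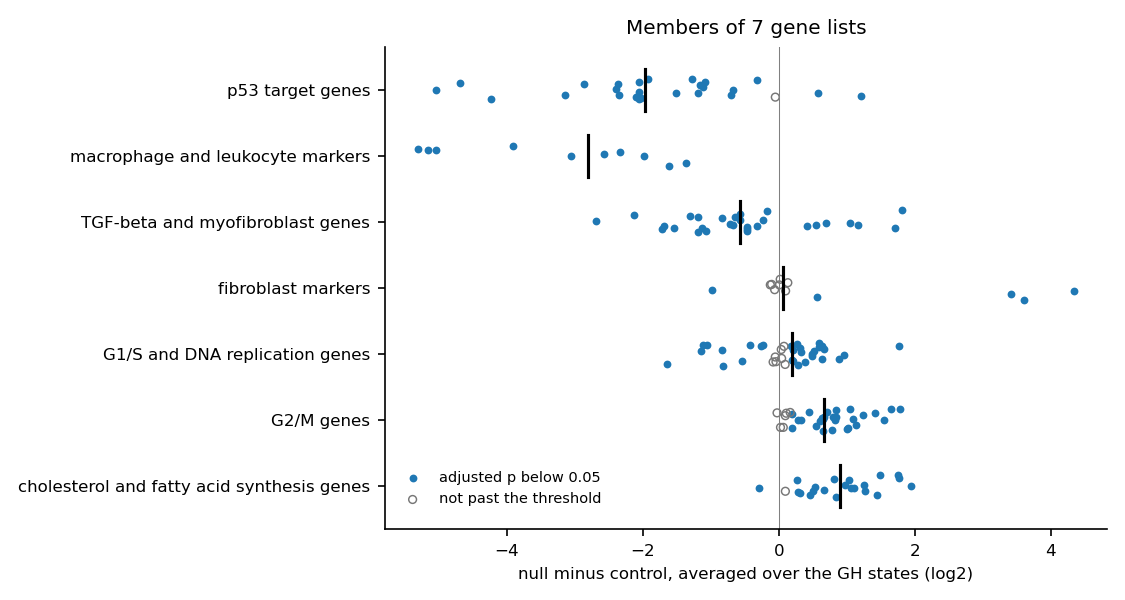
Log2 difference between null and control cells, averaged over the GH states (horizontal axis), for each measured member of 7 lists. Filled points passed the gene test, open points did not, and black bars are list medians, which lay at -1.97 for p53 targets, -2.81 for macrophage markers, -0.57 for TGF-beta genes, 0.06 for fibroblast markers, 0.19 for G1/S genes, 0.67 for G2/M genes and 0.90 for cholesterol genes.

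GH given to control cells for 2 hours raised the JAK-STAT feedback genes Cish, Socs2 and Socs3 and a larger set of inflammatory genes. The lists of STAT5 and GH target genes and of JAK-STAT components were not called in control cells. Cish rose 3.86-fold (1.95 ± 0.11, adjusted p = 2.26e-07), Socs2 2.64-fold (1.40 ± 0.10, adjusted p = 2.35e-06) and Socs3 4.56-fold (2.19 ± 0.11, adjusted p = 8.35e-08), and Bcl6 fell 1.83-fold (-0.87 ± 0.11, adjusted p = 0.000439, 1 of 2 probe sets past the test). The cell cycle inhibitors did not pass the test, at 0.11 ± 0.10 for Cdkn1a (adjusted p = 0.846) and -0.05 ± 0.09 for Cdkn2b (adjusted p = 0.956). Nor did Igf1 (0.19 ± 0.09), Stat5a (0.13 ± 0.18) or Stat5b (-0.09 ± 0.09) pass. Several genes rose from a level below the first quartile, so the size of their rise is not given. With their means under GH they were the neutrophil chemokine gene Cxcl2 (12.74), Acod1, which makes itaconate in activated macrophages (11.22), the chemokine gene Cxcl3 (8.81), the activation marker gene Cd69 (8.93) and the macrophage receptor gene Clec4e (9.84). Among genes that fell were the nuclear receptor gene Nr4a1 (-1.46 ± 0.09), Nfil3 (-1.43 ± 0.09), Id1 (-1.37 ± 0.11) and Chac1 (-1.35 ± 0.10), and Cd300lb fell from 6.72 to a level below the first quartile.

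Of 30 chemokine and inflammatory genes, 20 rose and none fell in control cells with GH (23 rose and 1 fell adjusted over the list alone, median 1.22). The chemokine gene Ccl5 (3.32 ± 0.09), the NF-kappaB inhibitor gene Tnfaip3 (3.86 ± 0.12) and the receptor gene Tlr2 (2.62 ± 0.10) were among them. STAT3 target and acute phase genes (8 rose and 1 fell of 22, the same adjusted over the list alone) and interferon response genes (9 rose and 1 fell of 36, 11 and 3 adjusted over the list alone) also shifted upward. Examples were Bcl3 (2.73 ± 0.11), Saa3 (3.29 ± 0.16) and Icam1 (3.21 ± 0.20) in the former and Irf1 (2.51 ± 0.10), Cxcl10 (4.67 ± 0.21), Parp14 (1.94 ± 0.11) and Gbp3 (2.14 ± 0.12) in the latter. The Cxcl10 mean without GH (6.12) lay close to the first quartile. The 3 list calls (adjusted p = 1.04e-53, 5.24e-10 and 4.35e-10) held with an estimated correlation (adjusted p = 0.00281, 0.0179 and 0.0179). Immediate early genes shifted downward (5 rose and 11 fell of 35, 9 and 13 adjusted over the list alone, adjusted p = 0.00787, and adjusted p = 0.446 with an estimated correlation). Among them were Zfp36 (1.51 ± 0.09) and Ier3 (1.43 ± 0.09) higher and Nr4a1 and Ccn1 (-0.99 ± 0.10) lower. With the mean of its probe sets Ccn1 stood at 0.12 and was not called (adjusted p = 0.704). The macrophage marker list, low in null cells, had Cd14 higher in control cells with GH (3.47-fold, 1.79 ± 0.10) and a median of 0.13 (1 of 10 rose, 3 adjusted over the list alone, adjusted p = 0.0191, and adjusted p = 0.446 with an estimated correlation).

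Further calls in control cells were lost with an estimated correlation. TGF-beta and myofibroblast genes shifted downward (6 of 29 fell, 1 rose and 6 fell adjusted over the list alone, adjusted p = 0.0181, and adjusted p = 0.403 with an estimated correlation), among them Id1 and Id3 (-0.94 ± 0.09). Small upward shifts were called for oxidative stress genes (1 of 18 rose, 7 adjusted over the list alone, median 0.13, adjusted p = 0.000106), HOX genes (2 of 30 rose, 2 adjusted over the list alone, median 0.13, adjusted p = 0.00473) and extracellular matrix genes (none of 37 passed, adjusted over the list alone or not, median 0.04, adjusted p = 0.0399). With an estimated correlation these had adjusted p = 0.176, 0.446 and 0.658. The other 18 lists were not called (adjusted p from 0.117 to 0.961). In total 476 genes responded in control cells, 313 upward and 163 downward. The count was 295 without the control array with GH numbered 2 and 316 without the one numbered 3. It was 316 in a fit on the 4 arrays compared, 170 without variance moderation, where Bcl6 was not called (adjusted p = 0.122), and 269 at a change of at least 1.5-fold.

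GH given to null cells left the STAT5 feedback genes near their level without GH and raised inflammatory genes. Cish (0.06 ± 0.11, adjusted p = 0.745), Socs2 (0.24 ± 0.10, adjusted p = 0.152), Socs3 (-0.02 ± 0.11, adjusted p = 0.915) and Bcl6 (0.14 ± 0.11, adjusted p = 0.459) did not pass the test in null cells. The acute phase gene Saa3 rose 55.3-fold (5.79 ± 0.16), Tnfaip3 21.2-fold (4.40 ± 0.12) and the monocyte chemokine gene Ccl7 17.8-fold (4.15 ± 0.10). Cxcl2 and the chemokine gene Cxcl5 rose from below the first quartile to 11.37 and 9.58. Among genes that fell were Id2 (-1.64 ± 0.10), Nr4a1 (-1.48 ± 0.09), Gper1 (-1.29 ± 0.10), Ppp1r3c (-1.21 ± 0.10) and Sybu (-1.21 ± 0.17). Cdkn1a (0.13 ± 0.10, adjusted p = 0.431) and Igf1 (0.24 ± 0.09, adjusted p = 0.116) did not pass, nor did Stat5a, which was dim in null cells with and without GH.

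Cdkn2b rose 1.36-fold in null cells with GH (0.45 ± 0.09, adjusted p = 0.00788). That call was lost without the null array without GH numbered 3 (adjusted p = 0.0609), without the null array with GH numbered 3 (adjusted p = 0.0672) and without variance moderation (adjusted p = 0.0538). Stat5b was lower with GH (-0.33 ± 0.09, adjusted p = 0.0341), a call lost when any 1 of the 4 null arrays or of the 2 control arrays with GH was left out (adjusted p from 0.0528 to 0.207). It was also lost with the replicate block (adjusted p = 0.0545), without variance moderation (adjusted p = 0.0749) and with the mean of the probe sets (adjusted p = 0.113), and the other Stat5b probe set, dim in null cells, did not pass (adjusted p = 0.658).

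In null cells 24 of 30 chemokine and inflammatory genes rose with GH and none fell (26 adjusted over the list alone, median 1.92), including Ccl8 (3.77 ± 0.10). STAT3 target and acute phase genes (14 rose and 1 fell of 22, 15 and 2 adjusted over the list alone) and interferon response genes (16 of 36 rose, 17 rose and 1 fell adjusted over the list alone) shifted upward too. Examples were Saa3 and Bcl3 (2.26 ± 0.11) in the former and Gbp2 (3.31 ± 0.10) and Irf1 (2.30 ± 0.10) in the latter. These 3 calls (adjusted p = 3.05e-51, 5.21e-17 and 1.46e-14) held with an estimated correlation (adjusted p = 0.00309, 0.0068 and 0.0068). JAK-STAT components shifted upward (10 rose and 1 fell of 22, the same adjusted over the list alone, adjusted p = 1.97e-06, and adjusted p = 0.172 with an estimated correlation). They were led by the cytokine receptor genes Osmr (1.43 ± 0.10) and Lifr (1.07 ± 0.13) and by Jak2 (0.87 ± 0.11). G2/M genes shifted downward, with 12 of 33 lower and none higher (15 adjusted over the list alone, median -0.21, adjusted p = 8.37e-06, and adjusted p = 0.172 with an estimated correlation). Macrophage markers were not shifted in null cells (median -0.05, 1 of 10 rose, 1 adjusted over the list alone, adjusted p = 0.497).

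The list of STAT5 and GH target genes was called upward in null cells (5 rose and 1 fell of 20, the same adjusted over the list alone, median 0.10, adjusted p = 0.0075, and adjusted p = 0.377 with an estimated correlation). The members that rose with the lowest p were the receptor gene Lifr, the kinase gene Pim1 (0.55 ± 0.09) and Myc (0.47 ± 0.09), of which Myc was not called without the null array with GH numbered 3 (adjusted p = 0.0522). Extracellular matrix genes (5 of 37 rose, 6 adjusted over the list alone, median 0.10, adjusted p = 5.13e-06) and growth factors and the IGF system (4 rose and 3 fell of 23, 5 and 3 adjusted over the list alone, median 0.10, adjusted p = 0.0158) had small upward shifts, lost with an estimated correlation (adjusted p = 0.502 and 0.473). The other 19 lists were not called (adjusted p from 0.06 to 0.896). In total 2130 genes responded to GH in null cells, 975 upward and 1155 downward. The count was 818 (520 upward, 298 downward) and 1034 (546, 488) without the null array with GH numbered 2 or 3, and 984 (517, 467) and 1344 (776, 568) without the null array without GH numbered 2 or 3. It was 705 without variance moderation (408, 297) and 564 at a change of at least 1.5-fold (387, 177). Tested singly, 4877 probe sets passed in null cells (3319, 1558) and 807 in control cells. Falls outnumbered rises with all arrays but not under these settings, so the majority direction in null cells was not settled.

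The response to GH was then compared between the genotypes by the interaction test. The rise of Cish was larger in control than in null cells by 1.88 on the log2 scale (interaction -1.88 ± 0.15, adjusted p = 1.74e-05), that of Socs3 by 2.21 (-2.21 ± 0.15, adjusted p = 5.22e-06) and that of Socs2 by 1.17 (-1.17 ± 0.14, adjusted p = 0.00042). Bcl6 differed in the other direction (1.01 ± 0.15, adjusted p = 0.00238). The responses of Cdkn1a (0.02 ± 0.14, adjusted p = 0.961), Igf1 (0.04 ± 0.13) and Stat5b (-0.24 ± 0.13) did not differ detectably, nor did that of Stat5a, dim in null cells. For Cdkn2b the interaction was 0.49 ± 0.13 (adjusted p = 0.0482), and leaving out any 1 of the 8 arrays ended the call (adjusted p from 0.0519 to 0.17). So did the replicate block (adjusted p = 0.081), no variance moderation (adjusted p = 0.132), equal array medians (adjusted p = 0.0581) and single tests of all probe sets (adjusted p = 0.0599).

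Inflammatory genes differed in both directions. The chemokine gene Ccl4 (-3.92 ± 0.13) responded more in control cells. So did Clec4e, the chemokine genes Ccl3 and Cxcl3 and the dendritic cell marker gene Cd83, whose levels in null cells lay below the first quartile with and without GH. In control cells Ccl3 stood at 7.38 without and 11.92 with GH. The chemokine gene Ccl8 (3.51 ± 0.14), the growth factor gene Ereg (2.56 ± 0.19), Noct (2.51 ± 0.13), Saa3 (2.50 ± 0.22) and Gch1 (2.39 ± 0.14) were named for a larger response in null cells. Ereg fell in control cells (-1.14 ± 0.13) and rose in null cells (1.42 ± 0.13). As a list, chemokines and inflammatory genes responded more in null cells (15 with a larger and 4 with a smaller response of 30, 17 and 6 adjusted over the list alone, adjusted p = 2.37e-09, and adjusted p = 0.0845 with an estimated correlation), while all 10 macrophage markers were lower in those cells.

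Immediate early genes also shifted toward a higher response in null cells (13 higher and 3 lower of 35, 16 and 5 adjusted over the list alone, adjusted p = 9.45e-05, and adjusted p = 0.308 with an estimated correlation). Among them were the transcription factor genes Fosl1 (1.65 ± 0.14), Maff (1.32 ± 0.14) and Atf3 (1.08 ± 0.12). STAT3 target and acute phase genes shifted the same way (7 higher and 1 lower of 22, 12 and 4 adjusted over the list alone, adjusted p = 9.45e-05, and adjusted p = 0.109 with an estimated correlation). So did JAK-STAT components, among them the phosphatase gene Ptpn1 (4 higher of 22, 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.000348, and adjusted p = 0.308 with an estimated correlation), and TGF-beta genes (5 higher and 1 lower of 29, 6 and 2 adjusted over the list alone, adjusted p = 0.0133, and adjusted p = 0.308 with an estimated correlation). Extracellular matrix genes (none past the test, adjusted over the list alone or not, adjusted p = 0.0211, and adjusted p = 0.779 with an estimated correlation) and cholesterol genes (none past the test, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0307, and adjusted p = 0.734 with an estimated correlation) were also called upward. G2/M genes shifted the opposite way (2 lower of 33, 3 adjusted over the list alone, adjusted p = 0.00198, and adjusted p = 0.308 with an estimated correlation). The other 19 lists were not called (adjusted p from 0.0784 to 0.947), and without the null array without GH numbered 2 the lists called numbered 5 in place of 8.

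Across all genes 938 had a response that differed by genotype (515 more positive and 423 more negative in null). The directions were nearer to even with quantile normalization (519 and 515) and equal array medians (467 and 452). Both genotypes raised 150 genes, where independent lists would share 16.8, and lowered 26, where 10.3 would be shared. For 83 of the 150 the interaction did not pass. A further 23 genes rose in control and fell in null cells, and 29 fell in control and rose in null cells. Across genes the GH responses of the genotypes, which share no array, correlated at 0.359. The interaction count was 586 and 561 without the control array with GH numbered 2 or 3, 437 and 459 without the null array with GH numbered 2 or 3. It was 585 without the null array without GH numbered 2, and 177 without variance moderation. Without moderation Socs2 (adjusted p = 0.0636) and Bcl6 (adjusted p = 0.117) were not called, and with each probe set tested alone 2469 probe sets passed, 1822 more positive and 647 more negative in null cells.

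**Figure D3:**
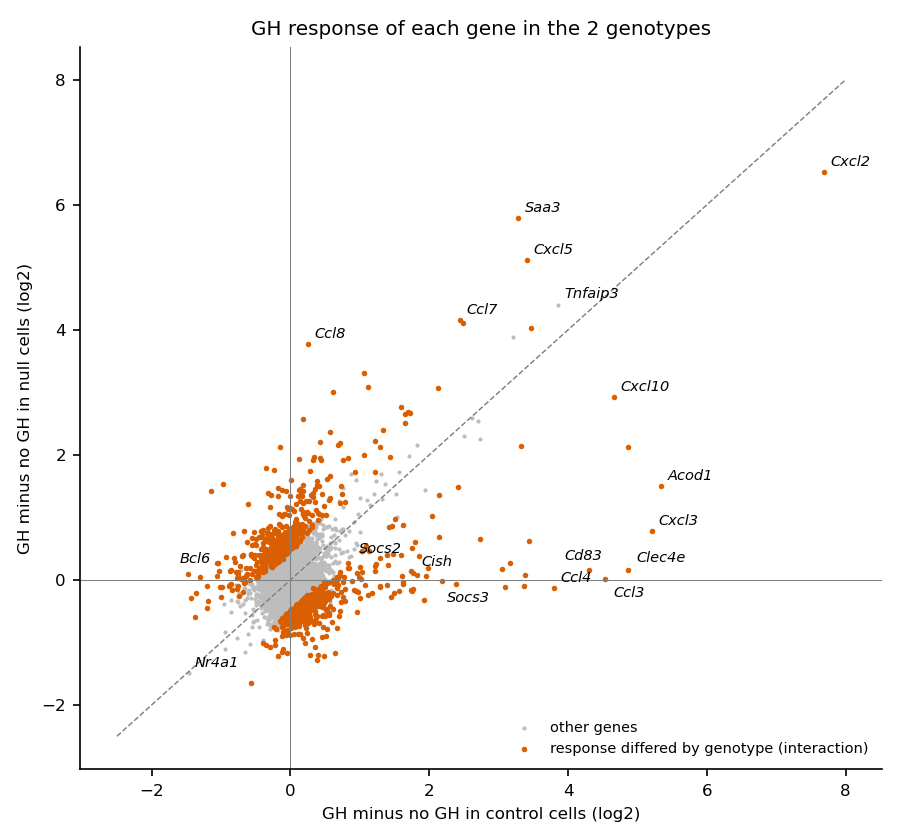
Log2 change with GH in control cells (horizontal axis) and in null cells (vertical axis), 1 point per gene, with the dashed line at equal change. Orange points are the 938 genes whose response differed between genotypes by the interaction test, such as Cish (1.95 in control, 0.06 in null) and Ccl8 (0.26 and 3.77), while Tnfaip3 rose in both (3.86 and 4.40).

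Averaged over the genotypes, GH changed 1314 genes (689 higher, 625 lower). Falls outnumbered rises with quantile normalization (704 higher, 791 lower) and equal array medians (652 higher, 735 lower). With each probe set tested alone, 3100 passed (2282 higher, 818 lower), so the direction with more genes was not settled. Saa3 (4.54 ± 0.11), Tnfaip3 (4.13 ± 0.08) and the interferon-induced chemokine gene Cxcl10 (3.79 ± 0.15) rose, as did Cxcl2 and Cxcl5 from a dim level. In control cells without GH the Cxcl10 mean (6.12) lay close to the first quartile. Nr4a1 (-1.47 ± 0.07), the G protein regulator gene Rgs2 (-0.89 ± 0.08, 1 of 4 probe sets not past), Nfil3 (-0.86 ± 0.06), Ankrd37 (-0.85 ± 0.08) and the iron exporter gene Slc40a1 (-0.70 ± 0.07) fell. Cish (1.01 ± 0.07), Socs2 (0.82 ± 0.07) and Socs3 (1.08 ± 0.08) rose in the average, which covers responses that differed by genotype. Cdkn1a (0.12 ± 0.07), Cdkn2b (0.20 ± 0.06, adjusted p = 0.0873), Igf1 (0.22 ± 0.06, adjusted p = 0.0655) and Stat5b (-0.21 ± 0.06, adjusted p = 0.0701) did not pass, nor did Stat5a. Some alternatives called these genes: a trended robust prior Cdkn2b (adjusted p = 0.0332) and Igf1 (adjusted p = 0.032), genes above the median only Cdkn2b (adjusted p = 0.0337) and Igf1 (adjusted p = 0.0238), and quantile normalization Stat5b (adjusted p = 0.0417). Bcl6 was lower (-0.37 ± 0.08, adjusted p = 0.0121), a call lost without the control array with GH numbered 3, the null array without GH numbered 3 or either null array with GH (adjusted p from 0.0507 to 0.0654), and without variance moderation (adjusted p = 0.142).

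Of the lists, 26 of 30 chemokine and inflammatory genes (27 adjusted over the list alone), 13 of 22 STAT3 target genes with 2 lower (15 and 2 adjusted over the list alone) and 15 of 36 interferon response genes (20 higher and 1 lower adjusted over the list alone) rose in the average. Their calls (adjusted p = 4.16e-66, 7.1e-20 and 2.65e-18) held with an estimated correlation (adjusted p = 0.00186, 0.00447 and 0.00447). The other 5 calls in the average were upward for JAK-STAT components, STAT5 and GH targets, oxidative stress and extracellular matrix genes and downward for G2/M genes (adjusted p = 9.75e-06, 0.00136, 0.000889, 2.74e-06 and 4.71e-05), and were lost with an estimated correlation (adjusted p = 0.19, 0.227, 0.19, 0.411 and 0.19). In these lists 5, 6, 4, 2 and 0 members rose and 2, 4, 0, 0 and 4 fell (9, 9, 4, 2 and 0 against 2, 5, 0, 0 and 11 adjusted over the list alone), and 19 lists were not called (adjusted p from 0.066 to 0.927). The count of genes was 864 and 709 without the control or the null array with GH numbered 2, 862 without the null array with GH numbered 3. It was 811 without the null array without GH numbered 2, 405 without variance moderation and 251 at a change of at least 1.5-fold (217 higher, 34 lower), and 3100 probe sets passed when each was tested alone (2282 higher, 818 lower).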

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

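The tests of the macrophage markers, of the fibroblast markers, of the inflammatory genes, of the STAT5 feedback genes and of exchanges of arrays within a genotype were chosen after the results were seen, and the tests on other splits of all arrays were planned. The results below came forward because the response to GH differed between the genotypes by a test of the difference itself, the interaction. It passed for 938 genes. The log2 interaction was 3.51 for Ccl8, 2.56 for Ereg, 2.51 for Noct, 2.50 for Saa3 and 2.39 for Gch1, whose response was more positive in null cells, and -3.92 for Ccl4, whose response was more positive in control cells. The deposited values also gave -4.52 for Ccl3, -4.15 for Cd83, -4.71 for Clec4e and -4.44 for Cxcl3 (in alphabetical order), but these 4 lay below the first quartile of gene values in null cells, so only the direction, and neither the size nor the order, is taken from them. Among the genes followed throughout it was 0.49 for Cdkn2b, -1.88 for Cish, -1.17 for Socs2, -2.21 for Socs3 and 1.01 for Bcl6. Groups of 2 arrays are too small to test for a single array far from the others.

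Other splits of the 8 arrays into 4 and 4 were counted for both averaged comparisons. For null against control, 1 of 35 splits, the real one, gave as many genes (8782, highest other 28), so a random arrangement of the arrays was excluded. The labels do not say whether the replicates came from separate cultures, so the splits cannot separate genotype from culture. For GH, 2 of 35 splits gave as many genes as the real one (28), and the other was the genotype split with 8782 genes, which is a structure of the samples. That test did not exclude chance for GH. With arrays exchanged only within each genotype, 1 of 18 splits, the real one, gave as many genes (390), and these splits are too few for a share under 0.05. The highest other split (54) is the one with the GH labels turned in 1 genotype, which is the structure of the interaction, and the remaining 16 gave 0.

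Macrophage and leukocyte markers were lower in null cultures, all 10 of the fixed list among them. Macrophages present in the control cultures and fewer in the null cultures may account for this, since all 10 were past the test in the same direction, and C1qa, C1qb and Mpeg1 (12.08, 11.77 and 11.05 in control cultures), looked up later, were lower too. Of 12 fibroblast markers, 9 were higher in null cultures by under 1 or lower, while Lum (4.35), Dcn (3.61) and Pdgfra (3.42) were far higher. Col1a1, Col1a2, Thy1, Vim and S100a4 stood at 14.01 or more in control cultures, near the top of the scale, with little room to rise. The others under 1 were Twist1 (0.57), Prrx1 (0.13), Pdgfrb (0.01) and Fap (-0.98). These values argue against such cells as the only cause of the genotype difference. STAT5 keeping the macrophage markers on within fibroblasts stays open: the median change of these markers with GH in control cells was 0.13, and bulk RNA does not assign a transcript to a cell. Genes with a larger control response, such as Clec4e, Ccl3 and Cd83, are expressed in macrophages, and a difference in cell content and one in signalling cannot be told apart for the markers here.

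Inflammatory genes rose with GH in null as in control cells. In null cells Cish, Socs2 and Socs3, which are outside the list, had a median change of 0.06 with GH. Each responded less than in control cells by the interaction test. The null cells lack Stat5a and Stat5b by design, so for Cish and Socs2 this test could hardly have come out otherwise. Socs3 is also a member of the STAT3 target and acute phase list. That list was called upward with GH in null cells, whereas Socs3 did not pass there (-0.02 ± 0.11). The test of these 3 genes does not show how the inflammatory genes rose. The list of STAT5 and GH target genes was called upward with GH in null cells, a call lost with an estimated correlation. Its members Lifr, Pim1 and Myc, which rose, are also in the JAK-STAT, STAT3 target and immediate early lists, respectively. Its members Cish, Socs2, Socs3 and Bcl6 did not pass in null cells. The changes of Cish, Socs2 and Socs3 argue against STAT5 activity in null cells as strong as in control cells. A weaker remaining activity was not tested. With GH, all 30 measured members had a median of 0.44 (SD of the members 1.72, 19 higher and 8 lower) above control cells. The macrophage markers stood at a median of -3.05. As a set, the inflammatory genes thus did not follow the macrophage markers in level. Which cells made these transcripts in null cultures stays open. Bulk RNA does not assign a transcript to a cell, and 4 of the fixed macrophage markers lay above the median gene in null cells. A part of the hormone preparation other than GH could have acted on both genotypes, and 18 members rose in both. Every stimulated array received the hormone, so this explanation and a STAT5-independent action of GH cannot be told apart.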

How the results depend on the processing

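The alternatives were planned except the crossed replicate block, which was chosen after the data were seen. The replicate block gave 8315 and 7957 genes for null against control without and with GH, 427 and 1713 for GH in control and null cells, 754 for the interaction, and 9676 and 1093 for the averages, with the counts of lists unchanged. Deviations from the group means of equally numbered arrays correlated between -0.279 and 0.129 across genes, so equal numbers did not mark a clear shared effect. Within a genotype the values were negative (-0.279 in control and -0.157 in null cells). A block with crossed numbers gave 553 (control) and 2559 (null) genes for GH, more than without a block. Whether differently numbered arrays share a culture or day was not tested. An estimated correlation left 0, 0, 3, 3, 0, 0 and 3 lists (without GH, with GH, GH in control, GH in null, interaction, genotype average, GH average) in place of 5, 6, 9, 8, 8, 5 and 8; the cause was not tested. A fit on only the 4 arrays compared gave 316 genes for GH in control cells, fewer than with all arrays, and 2353 in null cells and 8629 with GH, more than with all arrays; the cause was not tested. No variance moderation gave 170 genes for GH in control cells, 705 in null cells, 177 for the interaction and 405 for the GH average. Single tests of all probe sets, which are more than the genes, gave 17383, 16797, 807, 4877, 2469, 20810 and 3100 in the order above, and 12522 in both GH states. At least 1.5-fold was met by 4521, 4369, 269, 564, 4303 (genotype average) and 251 (GH average) genes, and by 3470 in both GH states in place of 6724, as fewer genes can pass. With the mean of probe sets Ccn1 reversed, to 0.12 for GH in control cells (from -0.99) and 0.064 in the GH average (from -0.63); the cause was not tested. With 1 array left out, counts ranged from 295 to 460 for GH in control cells (lowest without the control array with GH numbered 2, and 316 without the one numbered 3), 818 to 2409 for GH in null cells and 437 to 872 for the interaction (both lowest without the null array with GH numbered 2), 709 to 1236 for the GH average (lowest without the same array), 7633 to 8405 without GH, 6953 to 8477 with GH, 9196 to 9788 for the genotype average and 5966 to 6396 in both GH states. Lists called for the interaction ranged from 5 (without the null array without GH numbered 2) to 9. Calls gained were Cdkn2b and Igf1 in the GH average with a trended prior or above the median gene, Stat5b there with quantile normalization, and Igf1 in null cells above the median gene (adjusted p = 0.0496). No call among list members changed direction under quantile normalization or equal array medians. Signal near background was not set apart, which limits what dim genes can show.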

Other observations

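The tests of p53 target genes were planned, and the genes below were looked up after the results were seen. p53 target genes were lower in null cultures, 23 of 26 in the average over GH states. A change of Cdkn1a and Mdm2 alone was excluded, since the other 24 targets had a median of -1.71 (21 lower, 2 higher, camera adjusted p = 5.78e-10 in the place of the full list), a call lost with an estimated correlation (adjusted p = 0.12), as was that of the full list (adjusted p = 0.091). Lower p53 activity in the null culture could have arisen apart from the loss of Stat5a/b, for example during the 13 passages, and the 23 lower targets go with this explanation as with an effect of STAT5 itself. The 2 cannot be told apart, because each genotype was measured without a culture in which STAT5 was restored, and a contribution of macrophage RNA was not tested.

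Further values, averaged over the GH states as null minus control, were 2.13 for Igfbp4 and 2.02 for Igfbp6 among IGF-binding proteins, -4.13 for Gpx3 and 2.35 for Gstm1 among oxidative stress genes, 1.78 for the HOX gene Hoxa7, and -2.05 for Bbc3 and -1.04 for Bcl2l1 in the BCL2 family. These are single members of lists that were not called and that held members going both ways without GH. Bbc3 is also a member of the p53 target list, which was called lower in null cells. Ghr was higher by 1.11. The X-inactivation transcript Xist stood at 13.00 in control cells without GH. It was high on the null arrays too, at 12.644 and 12.405 without GH and 13.022 and 13.172 with GH.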
